A study of Danio rerio with 6 samples.

How the data were processed

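RNA was measured in 6 libraries of zebrafish (Danio rerio) fibroblasts, 3 from embryos injured on the trunk skin with acetic acid and 3 from uninjured controls. Per the labels' protocols, injury was made at 4 trunk sites at 2 days post fertilization (dpf), and trunks were taken at 3 dpf. About 30 embryos went into each biological replicate. Trunks were dissociated, 500 dsRed-positive cells were collected by flow cytometry, and cDNA was made with Smart-seq2, which copies polyadenylated RNA from small numbers of cells. Libraries were made by tagmentation with 12 cycles of amplification and sequenced in pairs of 150 bp reads, per the labels' protocols. Smart-seq2 libraries carry no molecular identifiers and no strand information, so amplified copies were counted as reads, and genes that overlap on opposite strands could not be separated. Each library stood for a separate pool of embryos, and p-values of single genes measured the spread between such pools.

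The values used were in TPM, read counts divided by transcript length and scaled to the same total in every library, which the authors deposited as a table of 32523 rows. Reads were aligned with STAR 2.7.10a to GRCz11, per the submitters' processing notes. The read counter, the annotation release and the handling of reads that map to several genes were not given in the sources used here. The 6 deposited files held the same table of all 6 libraries, and each column was matched to its library through the library name in the labels. Of the rows, 23014 carried a symbol in the file, 7009 were named from a table of gene identifiers, and 2500 had no name. Of the rows with a symbol, 3 were reporter sequences named mCherry, NTR and GFPSV40. They entered the TPM totals but not the tests. Gene coordinates were not used here.

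TPM keeps no depth by itself, but the deposited values moved in steps. For each row the values of the 6 libraries were searched for a common step that made them whole numbers of reads. Of the 102213 values above 0, 100% came out whole within 0.005 reads, and the recovered totals lay between 13715031 and 16051553 reads per library. Rows above 0 in few libraries can come out whole through the search alone, so for them this share is no test. The labels give an average of 8000000 raw reads per sample. The sources used here do not say why the recovered totals are higher, and the totals were used as relative depths and as the depth behind a value of 0. On simulated reads for the same rows, 98.35% of rows above 0 in at least 4 libraries were recovered exactly, and the largest error of a library total was 0.784%. Genes at 0 in every library of a group were above 0 in at most 3 libraries and lay outside that share. A gene at 0 in every library of a group was given the TPM of 3 reads per library as an upper limit, and a fold against it is written as at least that value. Such limits cover counting error only. If the 2 mates of a pair were counted as separate reads, the limit would be 2 times as high and these folds 2 times lower.

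Levels are given as mean TPM ± SD over 3 libraries. Genes with at least 1 TPM in at least 3 of the 6 libraries were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with an intensity trend and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this scale and understate the change of low genes. A gene under 1 TPM in every library of one group was tested only if all 3 libraries of the other group reached 1 TPM. The filter thus fixed the direction of such a gene, though not the size of its change. Every adjusted p of a gene comes from this limma model unless another is named. The test was tried on simulated counts of 12747 genes, of which 199 had known changes. It called 1.47% of 68 genes changed 2-fold, 24.2% of 66 genes changed 4-fold and 72.3% of 65 genes changed 16-fold. Of its calls 8.57% were unchanged genes. In this simulation smaller differences were therefore often not called. Fewer genes were changed in it than were called in the data, so these shares need not hold for the data. Single values were compared by exact two-sided permutation tests over 20 arrangements, whose smallest possible p is 0.1.

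Before the data were examined, 29 gene lists were fixed: signals and their receptors, matrix, stress, metabolism, and markers of fibroblasts and of other cell types of the trunk. Their 985 distinct members matched 935 rows, of which 751 were tested. Lists with at least 5 tested members were compared with all other tested genes by camera in limma with a preset correlation of 0.01, adjusted over the 29 lists. Its units are genes, so its p-values do not measure the spread between pools of embryos. Each list call was repeated with the correlation estimated from the data. Camera then also takes its p from the few degrees of freedom left by 6 libraries, not from the number of genes. A call lost in this setting can come from either change. Fry, which asks on its own whether a list's genes move one way on balance, was a further alternative.

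The rule for naming genes was also fixed then. It took the Cxcl12 ligands and receptors whatever their values. It took the 10 largest increases and the 10 largest decreases among changed genes whose groups did not overlap and whose higher mean was at least 5 TPM. It took up to 4 members of each list by smallest unadjusted p, and for other cell types up to 2 members with the highest TPM. A gene taken under several parts counted under each. Rows without a symbol were not named. Genes of near-identical families, such as mfap4.1 to mfap4.3, the actc1 and ckm copies, ribosomal protein genes and the tandem chemokine genes, can share reads, and the division of reads between copies is uncertain.

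The alternatives were pseudocounts of 0.1 and 5, no filter and a stricter filter of 5 TPM, trimmed-mean (TMM) scaling of TPM, quantile normalization, rescaling without the 13 mitochondrial-genome genes, array quality weights, limma without the trend, a minimum fold change of 1.5, the replicate number as a block, and leaving out each library in turn. Chosen after seeing the data were limma voom on the recovered reads, scaling to the mCherry row, and rescaling without the row of highest TPM. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.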

Results

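Fibroblasts sorted from the trunk of injured and uninjured zebrafish embryos were compared to ask how skin injury changes their transcripts, with the chemokine Cxcl12 and its receptors as the genes named in the title of the study. There were 3 libraries from embryos injured with acetic acid and 3 from untreated controls. The depth recovered from the TPM values was 13715031 to 15562843 reads per control library and 15326207 to 16051553 reads per injury library. Rows with at least 1 TPM numbered 12386 ± 188 in control and 13789 ± 139 in injury libraries (exact two-sided permutation p = 0.1, the smallest possible). Pearson correlations of log2(TPM + 1) across genes were 0.853 to 0.879 between libraries of a group and 0.676 to 0.723 between groups. The 13 rows named as mitochondrial-genome genes took 17.7% ± 1.01 of TPM in control and 16.8% ± 0.430 in injury libraries. The row of highest TPM has no name and was not among them. It took 10.8% ± 2.30 of TPM in control and 7.25% ± 0.290 in injury libraries, without overlap (exact permutation p = 0.1, the smallest possible). Values are means ± SD (n = 3 libraries per group).

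After injury, 25 of 26 tested leukocyte markers, 11 of 15 endothelial markers, 9 of 18 chemokine ligand genes and 14 of 30 inflammatory genes were higher. As lists these were called by camera with the preset correlation and not with an estimated one. Macrophage-associated mfap4.1 went from 2.23 ± 1.90 to 4719 ± 627 TPM, and the tumour necrosis factor gene tnfb from 0.697 ± 0.805 to 666 ± 222 TPM. Skeletal muscle transcripts went the other way, with the creatine kinase gene ckma at 254 ± 44.5 TPM in control and 0.0659 ± 0.00132 TPM in injury libraries. Of ribosomal protein genes 56 of 76 were lower, a list call that was lost with an estimated correlation, and limma without the trend called 0 of them (26 at an unadjusted p under 0.05). Of the collagen and structural matrix genes 10 of 41 were lower. Of the Cxcl12 genes, neither ligand passed the test, and the receptor gene cxcr4b was higher after injury, a call that was past the threshold in 8 of 19 alternatives and was lost without control replicate 1 or any single injury replicate.

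The ligand gene cxcl12a (ENSDARG00000037116) was at 83.6 ± 8.38 TPM in control and 117 ± 10.9 TPM in injury libraries. All 3 injury values lay above all 3 control values, the log2 fold change was 0.49 (SE 0.23), and the adjusted p was 0.213. An exact permutation test gave p = 0.1, the smallest possible with 3 libraries per group. Its paralog cxcl12b (ENSDARG00000055100) was at 111 ± 74.5 TPM in control and 44.6 ± 22.3 TPM in injury libraries, with a log2 fold change of -1.21 (SE 0.49), an adjusted p of 0.145 and an exact permutation p of 0.2. Control replicate 2 carried much of this difference, and without it the log2 fold change was -0.71. The receptor gene cxcr4b (ENSDARG00000041959) was at 25.3 ± 29.9 TPM in control and 241 ± 137 TPM in injury libraries and passed the test (log2 fold change 4.28, SE 1.16, adjusted p = 0.0377), while 25 of 26 leukocyte markers were higher in the same libraries. This call was close to the threshold and was past it in 8 of 19 alternatives. Without control replicate 1 its adjusted p was 0.0764, and without injury replicates 1, 2 and 3 it was 0.101, 0.161 and 0.122. Without control replicate 2 the log2 fold change was 2.73, and it stayed past the threshold.

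The other receptor genes gave no call. The paralog cxcr4a (ENSDARG00000057633) was at 4.83 ± 5.34 TPM in control and 0.597 ± 0.930 TPM in injury libraries (adjusted p = 0.356). The scavenger receptor gene ackr3b (ENSDARG00000058179) was at 63.6 ± 37.5 and 50.9 ± 1.111 TPM (adjusted p = 0.844), and without control replicate 3 its log2 fold change was 0.28 in place of -0.16. Its paralog ackr3a (ENSDARG00000062478), at 2.34 ± 2.18 and 0.265 ± 0.458 TPM, had too few libraries above 1 TPM to be tested.

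The size of the cxcl12a difference depended on the scaling of the libraries. The median log2 fold change of all tested genes was 0.32 on deposited TPM. It was 0.038 after TMM scaling, -0.13 after quantile normalization and -0.072 after scaling to the mCherry row. Relative to the median of all genes on deposited TPM, cxcl12a was higher by 0.17 and cxcl12b lower by a log2 value of -1.53. With the mCherry row as the reference, cxcl12a was at 0.0474 ± 0.0115 of mCherry in control and 0.0467 ± 0.00310 in injury libraries (exact permutation p = 1). For cxcl12b the ratio was 0.0595 ± 0.0317 and 0.0189 ± 0.0127 (exact permutation p = 0.1). The reporter rows did not move together. NTR over mCherry was 0.740 ± 0.0801 in control and 0.593 ± 0.0296 in injury libraries (exact permutation p = 0.1, the smallest possible). The ratios to mCherry thus depend on the choice of that row, and scaling to another reporter row was not tried. After quantile normalization cxcl12b passed the test, with a log2 fold change of -1.72 and an adjusted p of 0.0465, and over its 19 alternatives the adjusted p ranged from 0.0465 to 0.377.

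**Figure D1:**
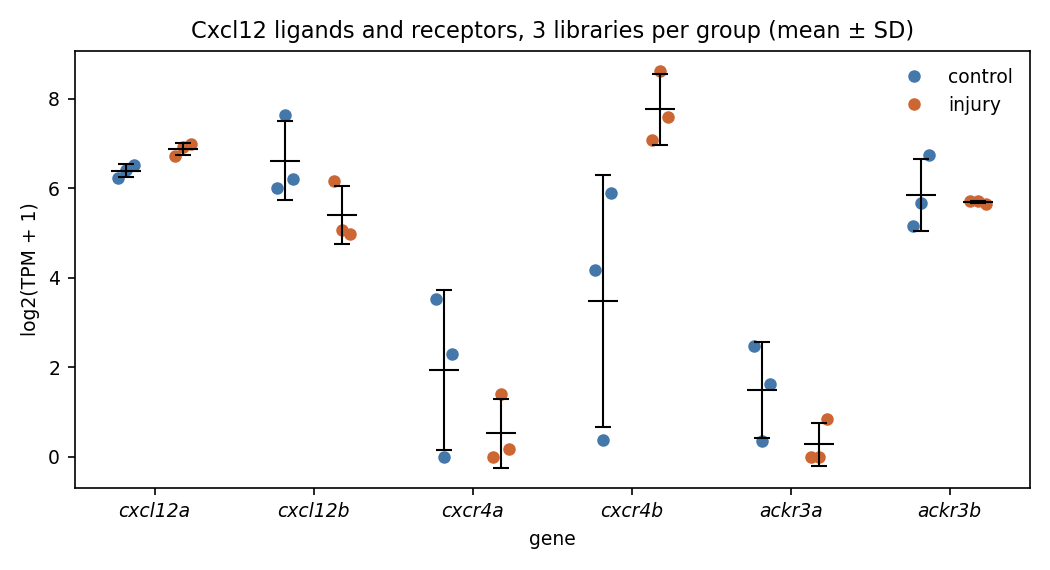
Points are single libraries and black bars the mean ± SD of 3 libraries, on log2(TPM + 1), for the Cxcl12 ligand and receptor genes in control and injury libraries. For cxcl12a and cxcr4b all 3 injury values lie above all 3 control values, while the other 4 genes overlap.

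Of 13779 tested genes, 1962 changed after injury, 1523 to higher and 439 to lower levels. In all 1962 the 3 injury values lay on one side of the 3 control values, as in 4380 of all tested genes (31.8%, where chance gives 10%). The largest increases were in mfap4.1, mfap4.2 and mfap4.3, which are close copies, and in the chemokine genes ccl34a.4 and ccl35.1. They also included the water channel gene aqp8b, the chemerin receptor gene cmklr1, the Fc receptor chain gene fcer1gl and the rows si:dkey-5n18.1 and LOC797571. Their log2 fold changes ran from 9.21 for ccl35.1 to 10.65 for mfap4.1. The gene ccl34a.4 went from 0.411 ± 0.229 to 1548 ± 530 TPM (adjusted p = 6.69e-07). The largest decreases were all in genes known from muscle: myl13, myl10, actc1a, actc1b, actc1c, ckma, ckmb, tnnc1b, pvalb4 and atp2a1, with log2 fold changes from -8.42 for myl13 to -6.35 for atp2a1. After voom on recovered reads the call of myl13 was lost. On deposited TPM 77.6% of changed genes were higher, against 62.3% after TMM scaling, 55.7% after quantile normalization, 62.3% after voom and 62.9% after scaling to mCherry. Without injury replicate 3, 1240 genes changed, 961 to higher and 279 to lower levels.

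Leukocyte markers formed the list with the largest change. Of its 26 tested members 25 were higher and 1 did not pass, and 26 were higher when adjusted over the list alone. Among them were the macrophage-associated genes mfap4.1 and cmklr1, the phosphatidylserine receptor gene havcr1 (0.132 ± 0.0610 to 440 ± 137 TPM) and the cathepsin gene ctss2.1 (0.0760 ± 0.0737 to 336 ± 126 TPM). The gene fcer1gl went from 2.42 ± 3.06 to 2346 ± 434 TPM. The tested members together held 320 ± 182 TPM in control and 12839 ± 2030 TPM in injury libraries. Of the 36 members of the list 32 were among the rows, and those with fewer than 3 libraries at 1 TPM were not tested. In control libraries 7 of the 26 tested members had a mean of at least 1 TPM. For members under 1 TPM in every control library the filter fixed the direction, so their number adds no support. Relative to the median of all genes the list median was higher by 5.85 (log2), and camera gave an adjusted p of 4.31e-28. With an estimated correlation the adjusted p was 0.0646.

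Endothelial markers were higher for 11 of 15 tested members, also when adjusted over the list alone, and 4 did not pass, in the same libraries in which 25 of 26 leukocyte markers were higher. The gene lyve1b, a hyaluronan receptor of lymphatic and some venous endothelium, had no reads in control and 134 ± 23.7 TPM in injury libraries, at least 514-fold higher. The membrane protein gene clec14a was at least 322-fold higher, with 59.9 ± 33.0 TPM after injury, and the mannose receptor gene mrc1a was at least 338-fold higher, with 25.03 ± 11.7 TPM. The fenestral diaphragm gene plvapb went from 2.56 ± 2.60 to 118 ± 44.6 TPM (adjusted p = 0.000285). Only 6 of the 15 members had a control mean of at least 1 TPM. The filter fixed the direction of members under 1 TPM in every control library. The list median was 3.28 above that of all genes (camera adjusted p = 1.39e-07), with an adjusted p of 0.0562 with an estimated correlation.

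Chemokine ligand genes rose in 9 of 18 tested members and fell in 2, and 7 did not pass; adjusted over the list alone 12 were higher and 3 lower. Besides ccl34a.4 and ccl35.1, ccl34b.1 went from 0.264 ± 0.168 to 632 ± 286 TPM. The gene ccl25b fell from 172 ± 53.3 to 3.05 ± 2.53 TPM (log2 fold change -5.53, SE 0.49, adjusted p = 0.000115). Without control replicate 1 or injury replicate 2, 1 ligand gene was lower. Among chemokine receptors 5 of 11 were higher, none was lower and 6 did not pass, with 6 higher when adjusted over the list alone. The receptor gene ccr9a went from 0.0987 ± 0.0749 to 94.5 ± 18.5 TPM. No reads of ccr2 and cxcr3.2 were found in control libraries, and they were at least 235-fold and at least 142-fold higher after injury. Control means of at least 1 TPM were seen in 10 of the 18 ligand genes and 7 of the 11 receptor genes. For members under 1 TPM in every control library the filter fixed the direction, so their number adds no support. Among the higher receptors ccr9a, ccr2, cxcr3.2 and ccr12a were such members, and the remaining one was cxcr4b. Camera gave adjusted p of 0.00115 for the ligands and 0.0241 for the receptors. With an estimated correlation the adjusted p was 0.0810 and 0.183. In the same injury libraries 25 of 26 leukocyte markers were higher.

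Inflammatory genes were higher in 14 of 30 tested members and lower in 1, with 17 and 2 when adjusted over the list alone, and 15 did not pass. The itaconate-producing enzyme gene acod1 rose from 0.0674 ± 0.117 to 342 ± 167 TPM, the galectin gene lgals9l1 from 2.53 ± 0.883 to 373 ± 146 TPM, and the colony-stimulating factor gene csf3b from 1.88 ± 1.83 to 415 ± 164 TPM. For tnfb the log2 fold change was 8.65 (SE 0.44, adjusted p = 5.4e-06). Of the 30 members 23 had a control mean of at least 1 TPM. The direction of members under 1 TPM in every control library, such as acod1, was fixed by the filter. The list median was 1.43 above that of all genes (camera adjusted p = 2.03e-05), with an adjusted p of 0.0777 with an estimated correlation. Interferon response genes were higher in 2 of 11, over all genes and over the list alone: irf7, from 11.82 ± 5.52 to 98.6 ± 63.5 TPM, and isg15, at least 36.0-fold higher. The list itself was not called (camera adjusted p = 0.112). In the same injury libraries 25 of 26 leukocyte markers were higher.

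Skeletal muscle markers fell in 25 of 28 tested members, none rose and 3 did not pass, and all 28 were lower when adjusted over the list alone. The cardiac-type actin gene actc1b, which is used in larval trunk muscle, fell from 1202 ± 328 to 9.91 ± 4.68 TPM. The creatine kinase gene ckmb fell from 298 ± 29.9 to 0.477 ± 0.427 TPM, and the calcium pump gene atp2a1 from 92.6 ± 25.4 to 0.122 ± 0.154 TPM (adjusted p = 3.6e-05). The 28 members together held 4189 ± 1594 TPM in control and 138 ± 44.8 TPM in injury libraries. All 28 had a control mean of at least 1 TPM. The filter fixed the direction of members under 1 TPM in every injury library. Relative to all genes the list median was -4.55 (log2; camera adjusted p = 3.28e-33). This was the only list called with an estimated correlation, with an adjusted p of 0.0180. Leaving out single libraries gave 19 to 23 lower members.

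Notochord and cartilage markers were lower in 5 of 16 tested members and higher in 1, with 6 and 1 when adjusted over the list alone, and 10 did not pass. The matrix protein gene matn4 fell from 257 ± 110 to 49.9 ± 3.33 TPM and the chondromodulin gene cnmd from 197 ± 63.2 to 44.3 ± 15.7 TPM. The exception was entpd5a, a nucleotidase gene needed for bone mineralization, which rose from 6.36 ± 4.78 to 90.2 ± 21.9 TPM (adjusted p = 0.00159). Camera gave an adjusted p of 0.00115 for a lower list, and with an estimated correlation the adjusted p was 0.329. Fry did not call the list (adjusted p = 0.141). Without injury replicate 1, 2 or 3 the number of lower members was 3. Leukocyte markers were higher in 25 of 26 members and skeletal muscle markers lower in 25 of 28 in these libraries.

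**Figure D2:**
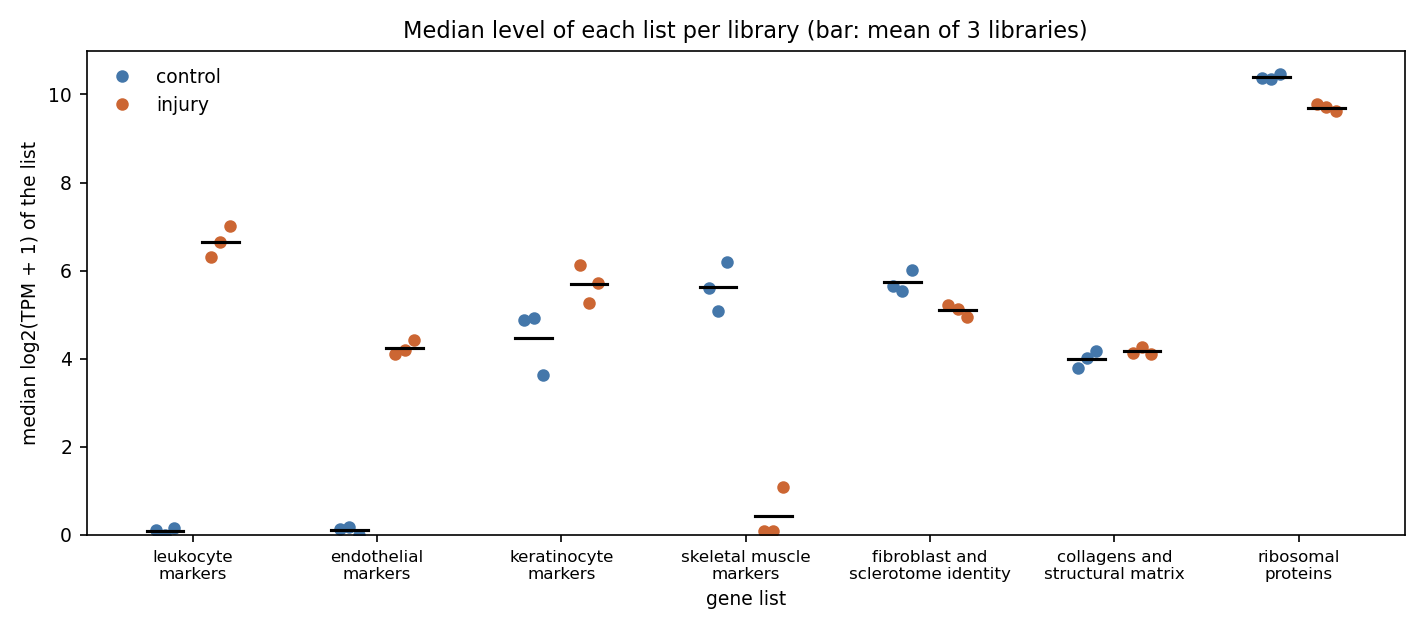
Points are libraries and bars the mean of 3 libraries, for the median log2(TPM + 1) over the tested members of 7 gene lists. Leukocyte and endothelial lists lie near 0 in control libraries and skeletal muscle near 0 in 2 of 3 injury libraries, while collagen levels overlap between groups although 10 single members were lower.

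Genes of the collagen and structural matrix list were lower in 10 of 41 tested members and higher in 2, with 15 and 5 when adjusted over the list alone, and 29 did not pass. The microfibril gene mfap2 fell from 1647 ± 68.6 to 456 ± 77.5 TPM (log2 fold change -1.86, SE 0.16, adjusted p = 8.42e-05). The periostin gene postnb fell from 597 ± 103 to 214 ± 40.1 TPM, the collagen gene col5a1 from 443 ± 73.7 to 159 ± 26.7 TPM and the decorin gene dcn from 631 ± 80.1 to 223 ± 57.0 TPM. The list median was -0.81 relative to all genes (camera adjusted p = 3.61e-05), and with an estimated correlation the adjusted p was 0.182. The median level over the list, on log2(TPM + 1), did not fall. It was 3.79, 4.02 and 4.18 in control and 4.14, 4.27 and 4.12 in injury libraries. After TMM scaling 16 members were lower and 1 higher. Of matrix proteases and inhibitors 6 of 24 were higher and 1 lower, 17 did not pass, and 8 were higher and 1 lower when adjusted over the list alone. The cathepsin genes ctsk and ctsba rose from 102 ± 26.7 to 1553 ± 796 TPM and from 42.6 ± 11.14 to 465 ± 95.8 TPM. The plasminogen activator gene plaua was at least 507-fold higher, at 67.6 ± 11.2 TPM after injury. This list was not called (camera adjusted p = 0.443). In the same injury libraries 25 of 26 leukocyte markers were higher.

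Genes of fibroblast and sclerotome identity were lower in 5 of 36 tested members and higher in 4, with 9 and 4 when adjusted over the list alone, and 27 did not pass. The fibroblast activation protein gene fap fell from 81.9 ± 25.9 to 9.37 ± 3.89 TPM, and the transcription factor gene twist1b from 140 ± 10.7 to 47.4 ± 4.66 TPM (adjusted p = 0.00255). The calcium-binding protein gene s100a10b went from 431 ± 172 to 1158 ± 228 TPM (adjusted p = 0.00584). Its call was lost after TMM scaling, in limma without the trend and after scaling to mCherry. The list median was -0.87 relative to all genes (camera adjusted p = 9.47e-05), with an adjusted p of 0.155 with an estimated correlation. Without control replicate 2 or 3 or any single injury replicate, 1 member was higher. After TMM scaling 10 were lower and 1 higher, after quantile normalization 13 and 1, by voom 11 and 2, and after scaling to mCherry 9 were lower and the higher calls were lost. Fry did not call the list (adjusted p = 0.0547). Leukocyte markers were higher in 25 of 26 members in the same injury libraries.

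Among stress genes, p53 targets rose in 13 of 24 tested members and fell in none, with 17 and 1 when adjusted over the list alone, and 11 did not pass. The pro-apoptotic gene pmaip1 went from 65.4 ± 14.2 to 481 ± 220 TPM and rps27l from 236 ± 80.3 to 896 ± 32.5 TPM. The lysosomal protease gene ctsd went from 88.5 ± 11.7 to 1187 ± 159 TPM. Oxidative stress genes rose in 12 of 29, with 16 higher and 1 lower over the list alone, and 17 did not pass. The ferritin gene fthl27 rose from 4312 ± 388 to 10745 ± 291 TPM and the heme oxygenase gene hmox1a from 33.4 ± 20.6 to 399 ± 162 TPM. Of the genes of endoplasmic reticulum stress and the amino acid response 13 of 35 rose and 1 fell, with 18 and 1 over the list alone, and 21 did not pass. The transcription factor gene ddit3 rose from 55.5 ± 7.75 to 233 ± 72.7 TPM. Camera gave adjusted p of 9.47e-05, 0.00116 and 0.000463 for the 3 lists. With an estimated correlation the adjusted p was 0.0727, 0.2002 and 0.2002. Leaving out single libraries gave 5 to 11 higher p53 targets, fewest without injury replicate 1 or 3. It gave 7 to 13 higher oxidative stress genes, fewest without injury replicate 3, and 5 to 11 higher endoplasmic reticulum stress genes, fewest without injury replicate 2. After TMM scaling, quantile normalization, voom and scaling to mCherry the p53 list had 8, 7, 8 and 6 higher members and the endoplasmic reticulum list 5, 5, 6 and 2. In limma without the trend each had 7. Heat shock genes rose in 4 of 23 and fell in 1 (4 and 2 over the list alone; camera adjusted p = 0.871), with 2 higher without control replicate 2 or any single injury replicate. After TMM scaling 1 heat shock gene was higher and 2 lower, by voom 2 and 2, and after scaling to mCherry 2 were lower and the higher calls were lost. The gene hsp90aa1.1, whose product serves myosin folding in muscle, fell from 84.3 ± 34.4 to 1.301 ± 0.173 TPM. Beside these changes, 25 of 26 leukocyte markers and 11 of 15 endothelial markers were higher and 25 of 28 skeletal muscle markers lower in injury libraries.

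Ribosomal protein genes fell in 56 of 76 tested members and rose in none, with 67 lower when adjusted over the list alone, and 20 did not pass. The gene rps20 fell from 16763 ± 615 to 9386 ± 319 TPM (log2 fold change -0.84, SE 0.07, adjusted p = 8.92e-05) and rpl6 from 9071 ± 546 to 4807 ± 120 TPM. Relative to all genes the list median was -1.002 (camera adjusted p = 3.46e-47), with an adjusted p of 0.0777 with an estimated correlation. In limma without the trend 0 of the 76 passed, with 26 at an unadjusted p under 0.05 and an adjusted p of 0.155 for rps20. Cell cycle genes were lower in 3 of 45, with 2 over the list alone, none was higher and 42 did not pass. The chromatin protein gene hmgb2b fell from 2218 ± 203 to 1022 ± 133 TPM, and mki67 was at 27.3 ± 5.56 and 8.61 ± 2.54 TPM. The call of mki67 was lost without any single library but injury replicate 2, and that of hmgb2b in limma without the trend. Without injury replicate 1, 1 cell cycle gene was lower, against 9 after TMM scaling, 10 after quantile normalization and 9 by voom. Fry did not call the list (adjusted p = 0.0792). The cell cycle list median was -0.82 relative to all genes (camera adjusted p = 6.19e-07), with an adjusted p of 0.190 with an estimated correlation. Both lists changed in libraries in which 25 of 26 leukocyte markers were higher and 25 of 28 skeletal muscle markers lower after injury.

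Oxidative phosphorylation genes rose in 13 of 51 tested members and fell in none, with 22 higher when adjusted over the list alone, and 38 did not pass. The gene cox6b1 rose from 80.5 ± 44.6 to 289 ± 23.8 TPM (adjusted p = 0.00521). Of the hypoxia and glycolysis list 8 of 37 were higher and 3 lower, with 12 and 3 over the list alone, and 26 did not pass. The phosphofructokinase regulator gene pfkfb3 rose from 4.01 ± 1.93 to 37.2 ± 12.8 TPM, and ankrd37 was at least 36.3-fold lower, with 10.6 ± 8.10 TPM in control. Camera gave adjusted p of 1.92e-06 and 0.0220, and with an estimated correlation the adjusted p was 0.325 and 0.356. After scaling to mCherry neither list was called (adjusted p = 0.160 and 0.0501), and without injury replicate 3 the hypoxia and glycolysis list was lost (adjusted p = 0.123) with 2 higher members. Leaving out single libraries gave 6 to 17 higher oxidative phosphorylation genes, fewest without any one injury replicate. There were 4 after TMM scaling, 6 after quantile normalization, 3 by voom, 2 after scaling to mCherry and 2 in limma without the trend. For hypoxia and glycolysis, 13 were higher and 1 lower without control replicate 3, 2 and 2 without injury replicate 2, 5 and 3 after quantile normalization, 3 and 2 in limma without the trend, and 1 and 3 after scaling to mCherry. The same libraries had 25 of 26 leukocyte markers higher and 25 of 28 skeletal muscle markers lower after injury.

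Of ligands that act on melanocytes, 1 of 10 tested members passed: the endothelin gene edn1 rose from 0.195 ± 0.337 to 35.5 ± 13.8 TPM (log2 fold change 4.89, SE 0.53, adjusted p = 0.000363), while 11 of 15 endothelial markers and 25 of 26 leukocyte markers were higher in the same libraries. Adjusted over the list alone 3 were higher and 3 lower. Over all genes, 1 was higher and 3 lower after quantile normalization, 1 and 2 after TMM scaling or by voom, and 1 and 1 with the replicate block. Without control replicate 3, 2 were higher. The colony-stimulating factor gene csf1b was at 53.1 ± 12.0 TPM in control and 11.4 ± 12.4 TPM in injury libraries (adjusted p = 0.0743), and bmp4 was at 91.8 ± 15.7 and 50.4 ± 8.28 TPM (adjusted p = 0.0734). Both passed after quantile normalization, csf1b also with a pseudocount of 5 and without injury replicate 1, and bmp4 also after TMM scaling, voom and scaling to mCherry. The receptor gene csf1ra was on the lists of other pigment cells and of leukocytes, not of melanocytes. An action of csf1b on melanocytes thus rests on the fixed list alone. The Wnt inhibitor gene dkk1b was at 9.01 ± 1.94 and 34.1 ± 25.6 TPM (log2 fold change 1.59, adjusted p = 0.0820), without overlap between groups, and passed in none of its alternatives. The list was not called (camera adjusted p = 0.563). Its median change was -0.43 and ran from -0.95 to 0.27 when single libraries were left out.

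Melanocyte markers were not called as a list (7 tested, 1 higher, over all genes and over the list alone; camera adjusted p = 0.142). The list was called lower with no filter (adjusted p = 0.0130) and without control replicate 2 (0.0146) or 3 (0.0334). The tetraspanin gene tspan36 rose from 194 ± 104 to 1090.3 ± 304 TPM. The pigment genes pmela, tyrp1b and slc45a2 were high in control replicate 1 alone, with 513, 700 and 119 TPM, and their adjusted p was 0.407, 0.422 and 0.416. Without this library the list median was 0.018 in place of -1.80. Among other pigment cell markers, 1 of 11 was higher, over all genes and over the list alone: the transcription factor gene tfec, from 0.400 ± 0.573 to 90.6 ± 31.2 TPM (list adjusted p = 0.609), in libraries in which 25 of 26 leukocyte markers were higher.

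**Figure D3:**
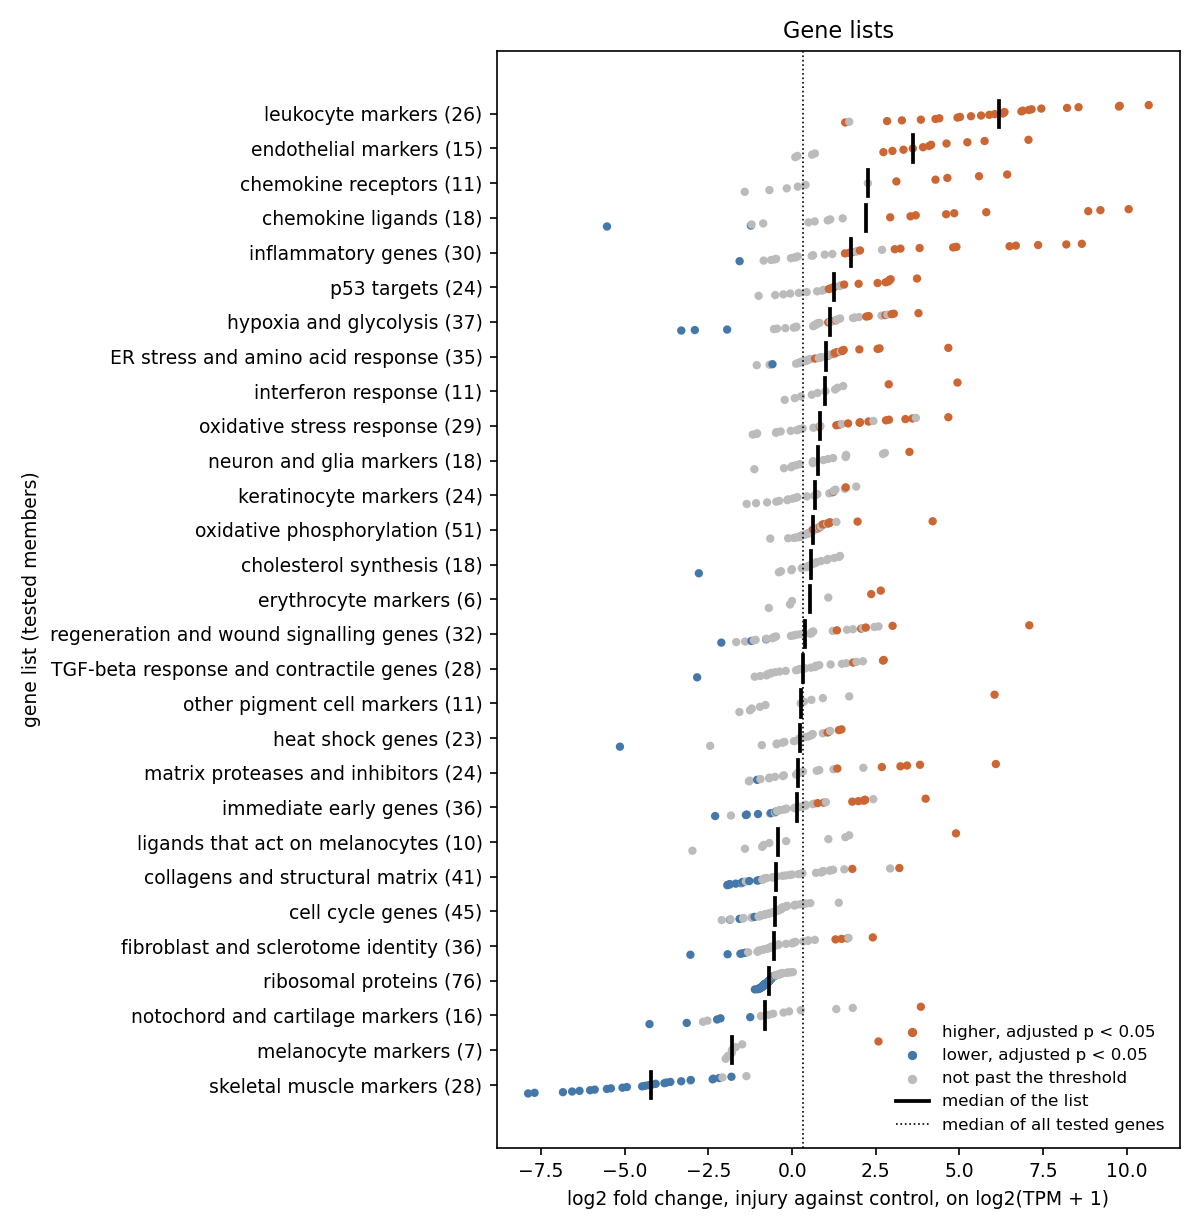
Each point is a tested gene of one of 29 lists, at its log2 fold change on log2(TPM + 1), coloured by its adjusted p; black bars are list medians and the dotted line is the median of all tested genes, 0.32. The leukocyte list (median 6.17) and the skeletal muscle list (median -4.23) lie farthest from it.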

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

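The tests of leukocyte RNA, depth, dilution, muscle RNA and library scaling were chosen after the results were seen, whereas the gene length test and the count over other splits were fixed before theirs.

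A signal appeared in rows outside the gene comparison: the mCherry row was 1.405 times as high in injury (2533 ± 376 TPM) as in control libraries (1803 ± 285 TPM). All 3 injury values lay above the control values (exact permutation p = 0.1, the smallest possible). The labels name dsRed as the marker of the sort. The NTR row stood at 1328 ± 203 TPM in control and 1497 ± 176 TPM in injury libraries (exact permutation p = 0.4), and GFPSV40 at 219 ± 60.3 and 333 ± 56.1 TPM (exact permutation p = 0.2).

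Leukocyte markers were higher in injury libraries although the sort took dsRed-positive cells. Greater depth is argued against, since recovered reads per injury library were 1.05 times those of control libraries. RNA of leukocytes among the sorted cells and a rise of these genes in the fibroblasts themselves cannot be told apart here. The 96.2% of tested markers that were higher is the pattern itself and would follow from either, and a sum over 500 cells cannot place the RNA in one cell type.

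Skeletal muscle transcripts were lower in injury libraries. Dilution by RNA of other cells is argued against as the whole cause. The median log2 change of muscle markers lay below that of the fibroblast and sclerotome list by -3.68. Permutation of genes between these lists gave p = 1e-04, the smallest that 10000 permutations give. It does not measure the spread between pools of embryos. More muscle RNA among the cells sorted from control embryos and loss of muscle transcripts through the injury itself cannot be told apart here, since the 89.3% of tested muscle markers that were lower is the pattern itself and would follow from either.

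Ribosomal protein transcripts were lower in injury libraries. The scaling test, on the list median relative to all genes, decides nothing where each library has one factor, since the median of all genes nearly cancels such a factor. After quantile normalization it gave -0.48, short of the bound written for it. The list median itself was -0.68 on deposited TPM, -1.03 after TMM scaling, -0.60 after quantile normalization and -1.17 after scaling to mCherry, with 56, 71, 63 and 58 of 76 genes lower. The size of the change thus depended on the scaling, which stays open as a contributor. Gene length bias is argued against, since the list median of -0.68 was at percentile 0 of 10000 random lists matched on length and mean expression, whose medians ran from -0.39 to 0.50. A different mixture of cell types and a response of the fibroblasts to injury both stay open and may act together.

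The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 1962 changed genes and the highest other gave 0 in limma, with 3707 genes at an unadjusted p under 0.05 in the real one and 341 to 496 in the others. Every other division mixed control and injury libraries on both sides. The difference between the groups then entered the spread within a side, which lowers the calls. The contrast therefore does not measure chance. For gene lists the real division gave 16 and the highest other 15. In each case 1 division, the real one, reached the real count.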

How the results depend on the processing

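Limma voom on recovered reads, scaling to the mCherry row and rescaling without the row of highest TPM were chosen after seeing the data. Of 107 named genes past the threshold, 75 stayed past it in each of the 19 alternatives for single genes in which they were fitted. The minimum fold change was applied to the number of changed genes and not to named genes. Of 16 called lists 14 were called under each alternative of the values, filter and libraries. Scaling to mCherry ended the calls of oxidative phosphorylation and of hypoxia and glycolysis, and leaving out injury replicate 3 ended the latter. With an estimated correlation 1 list was called in place of 16. The estimate was -0.031 for chemokine ligands, 0.0035 for chemokine receptors, -0.016 for endothelial markers and 0.00026 for p53 targets. For these lists a correlation above the preset 0.01 is argued against as the cause of the lost call. For the other lost lists the estimate was above 0.01, but the degrees of freedom of the test fell as well, and these changes were not separated. Fry called 17: it lost cell cycle, fibroblast and notochord genes and gained interferon response, matrix protease, other pigment and erythrocyte genes. Other causes of these differences were not tested. Melanocyte markers gained a call with no filter and without control replicate 2 or 3, and immediate early genes without injury replicate 2.

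The number of changed genes fell from 1962 to 1204 (960 higher, 244 lower) with no filter. More genes then entered both the fit and the adjustment, and their effects were not separated. It fell to 1068 (900 and 168) with a minimum fold change of 1.5, which asks for more by construction. Leaving out single libraries gave 1240 to 1711 changed genes, 961 to 1398 higher and 279 to 325 lower, from fewer samples. The lower genes numbered 701 after TMM scaling, 832 after quantile normalization and 290 in limma without the trend, against 439. The higher genes numbered 1007 by voom and 923 after scaling to mCherry, against 1523. The median of all tested genes was lower under TMM scaling, quantile normalization and scaling to mCherry than on deposited TPM. Of the 1962 genes, 1598 were called after TMM scaling and 1349 by voom.

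For cxcl12a the log2 fold change ran from 0.00073 (scaled to mCherry) to 0.56 without passing the test. For cxcl12b it was -1.72 after quantile normalization, where it passed; the cause was not tested. Leaving out single libraries gave -1.59 to -0.71.

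No list or gene that changed sign was called in the main test, on deposited TPM with the filter of 1 TPM and all 6 libraries. Melanocyte markers and immediate early genes, which changed sign, were called in the alternatives named above. Fry called 1 list that changed sign, other pigment cell markers (higher, adjusted p = 0.0294). The cholesterol list changed direction in camera with a pseudocount of 5 (median 0.30), a filter of 5 TPM (0.69), array weights (0.49) and without control replicate 1 or 3 or injury replicate 1 or 3 (0.29 to 0.73 over all 6 left-out libraries). Heat shock turned after TMM scaling (-0.089), voom (-0.10), scaling to mCherry (-0.22) and without injury replicate 1 (0.24 to 0.39 over all 6). Melanocyte markers turned without control replicate 1 (-2.71 to 0.018 over all 6) and keratinocyte markers without control replicate 3 (0.28 to 0.89). Fry gave the other direction than camera for melanocyte ligands (-0.43), TGF-beta (0.31), regeneration (0.39), immediate early (0.16) and other pigment genes (0.25). Camera compares a list with all genes and fry compares it with 0. For epcam the log2 fold change was -0.34 (TMM), -0.19 (quantile), -0.00038 (without mitochondrial genes), -0.30 (voom), -0.48 (mCherry), -0.042 (without the highest row) and -0.20 to 0.14 over left-out libraries. Over left-out libraries it ran from -0.51 to 0.28 for ackr3b, -0.66 to 0.067 for icn, -2.46 to 0.018 for tyrp1b, -0.81 to 0.61 for stmn1b and -1.08 to 0.038 for hbae1.3. The cause was not tested.

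Whether the replicate numbers pair the libraries could not be settled with 3 libraries per group. Deviations of same-numbered samples correlated only weakly, at 0.023, 0.022 and 0.011, but each sample correlated best with its own number. With the replicate block 1707 genes changed (1327 higher, 380 lower), 1632 of them among the 1962, and the 16 list calls were kept. On simulated counts, in which 199 of 12747 genes were changed, most differences of 2-fold were not called. In the data smaller differences could pass, as for rps20 with a log2 fold change of -0.84 (limma adjusted p = 8.92e-05). Of ribosomal protein genes 56 of 76 were lower, with a list median of -0.68.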

Other observations

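Several gene groups held strong single changes without a call of the whole list. Of the regeneration and wound signalling list, 5 of 32 tested genes were higher and 3 lower, with 8 and 4 when adjusted over the list alone, and 24 did not pass (camera adjusted p = 0.563). The galectin gene lgals2a rose from 3.08 ± 4.91 to 333 ± 27.9 TPM, and the retinoic acid binding protein gene crabp2a fell from 751 ± 53.8 to 180 ± 64.4 TPM (log2 fold change -2.11, SE 0.25, adjusted p = 0.000575). Immediate early genes moved both ways, with 8 of 36 higher and 6 lower, 9 and 8 when adjusted over the list alone, and 22 not passing (camera adjusted p = 0.258). The CCAAT/enhancer-binding protein genes cebpb and cebpd went apart, cebpb from 354 ± 50.5 to 1264 ± 393 TPM and cebpd from 2193 ± 199 to 849 ± 163 TPM, and the phosphatase gene dusp5 rose from 99.6 ± 26.8 to 455 ± 120 TPM. Without injury replicate 2 or 3 the number of higher immediate early genes was 3, and without injury replicate 3 that of regeneration genes was 1. The balance depended on scaling: 6 immediate early genes were higher and 8 lower after TMM scaling, 5 and 7 after quantile normalization, 4 and 9 by voom, and 4 and 7 after scaling to mCherry. Without injury replicate 2 the immediate early list was called lower (adjusted p = 0.0330). Of the regeneration genes 2 were higher and 4 lower after TMM scaling, 2 and 3 after quantile normalization, and 1 and 3 by voom or after scaling to mCherry.

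In the list of TGF-beta response and contractile genes 3 of 28 were higher and 1 lower, with 4 and 2 when adjusted over the list alone, and 24 did not pass (camera adjusted p = 0.672). After TMM scaling, quantile normalization or scaling to mCherry 3 were higher and 4 lower, and by voom 3 and 5. The actin-binding protein genes tagln and tagln2 rose from 27.3 ± 19.7 to 159 ± 22.7 TPM and from 58.8 ± 8.26 to 210 ± 18.8 TPM. The 1 cholesterol synthesis gene of 18 that passed, over all genes and over the list alone, was the lipoprotein receptor gene ldlra, which fell from 50.2 ± 18.8 to 7.09 ± 4.63 TPM (list adjusted p = 0.986). For the regeneration, TGF-beta and immediate early lists the median and mean were above 0 while camera pointed lower. In the libraries compared here, 25 of 26 leukocyte markers were higher and 25 of 28 skeletal muscle markers lower after injury.

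Markers of the remaining cell types were not called as lists. Keratinocyte markers were higher in 2 of 24, with 1 when adjusted over the list alone (camera adjusted p = 0.563), and the abundant epcam stood at 630 ± 150 TPM in control and 627 ± 79.3 TPM in injury libraries. The number of higher keratinocyte markers was 4 without control replicate 1 and 1 without control replicate 2 or any single injury replicate. The calls were lost after TMM scaling, quantile normalization and scaling to mCherry and in limma without the trend. Neuron and glia markers were higher in 1 of 18, over all genes and over the list alone (adjusted p = 0.420), and that gene, fabp7a, was not past the threshold without control replicate 1 or 3 or without injury replicate 1 or 2. Erythrocyte markers were higher in 2 of 6, over all genes and over the list alone (adjusted p = 0.443), with the biliverdin reductase gene blvrb at 13.97 ± 6.25 and 91.4 ± 32.3 TPM. Without any single control replicate or injury replicate 1 or 3, 1 erythrocyte marker was higher.

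The leukocyte markers that rose included the macrophage-associated genes mfap4.1 and cmklr1. The neutrophil genes mpx and lyz, members of the same list singled out after their values were seen, were too low to be tested: mpx was at 0 TPM in every control library and at most 0.370 TPM after injury, and lyz at most 0.675 and 0.853 TPM.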
